A study of Mus musculus with 9 samples.

How the data were processed

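RNA from prominin-1-positive kidney cells of C57BL/6 mice, described by the labels as kidney proximal tubule, was sequenced in 9 libraries. The groups were sham-operated adult males, sham-operated females and ovariectomized females, with 3 libraries each that the labels call biological replicates. Both female groups were operated on at postnatal day 21, and the labels used here give no day of surgery for the males. Cells of the cortex were dissociated, labelled with an antibody against prominin-1 (the product of Prom1, a membrane protein of the brush border) and retained on a magnetic column. RNA was prepared with an RNeasy kit, and strand-specific libraries were made with the NEBNext Ultra II Directional kit. The submitters list STAR 2.6.0c and RSEM as processing tools. The RSEM version, the genome build and the gene annotation are not given in the sources used here.

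The table deposited by the authors holds FPKM, fragments per kilobase of transcript per 1e6 mapped fragments, per gene and library, with 2 decimals. No scaling between libraries is stated, and the values were used as deposited. The table has 52405 entries with an Ensembl gene ID and a symbol, and 52093 of the IDs were found in the GENCODE M21 annotation (mouse build GRCm38), which supplied the positions. Among the entries, 71 symbols stand on more than 1 line, and those lines were kept apart by their ID. Of 4 unnamed side columns, 3 held 24 numbers, of which 18 equalled the FPKM of Igf1r or its log2. The side columns were not used. Reads were not analysed here.

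The table gives no read counts, so the depth was estimated from the steps between low FPKM values of genes with a single transcript of 300 to 800 bp. A grid search over the number of reads and an offset on the length sought values that fall within 0.0055 FPKM of 1 to 3 reads. The estimates were 21.5 to 28.25 M (1e6) reads per library with an offset of 70 to 80 bp. At the best fit 55.6% to 58.4% of the values fell on these steps, against 11.2% to 14.8% by chance. FPKM sums were 693451 to 734990, and mitochondrially encoded genes made up 24.6% to 27.3% of them. Because these are estimates and not counts, no counting intervals were computed.

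Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were tested, 13160 in all. Values were transformed to log2(FPKM + 1) and fitted with limma 3.58.1 in R 4.3.3, in 1 fit with a mean per group and a trended empirical Bayes variance. Tests were two-sided with the Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Counts of genes that also changed by 2-fold or more are given beside these. Means are given with the SD over the 3 libraries, and log2 fold changes are those of the fit. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

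In total 43 gene lists were fixed, covering sex chromosome genes, genes known from earlier work as higher in male or female mouse kidney, hormone receptors and signalling, transporters, metabolism, detoxification, stress and injury, immunity, transcription factors, mitochondrial genes, matrix genes, and markers of kidney cell types and other tissues. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists, and called at an adjusted p under 0.05. Beside it stand camera with an estimated correlation and fry, a rotation test whose p asks whether a list's genes move, on balance, one way. Camera sets a list against all other genes tested, so up and down are relative to those. The median log2 fold change of all genes tested was -0.089, 0.007 and -0.088 in the 3 comparisons below. A list with a small median can thus be called up without a rise. Lists with at least 3 tested members were tested, 42 in all. The markers of T, B and NK cells and neutrophils had 0 tested members of 14 and gave no value. Within each list, members were also adjusted over the list alone.

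Genes are named by a fixed rule. Per comparison these are the 8 genes with the largest log2 fold change in each direction among called genes whose libraries separate fully and whose mean is at least 5 FPKM in the higher group, leaving out predicted genes. From each list with 2 or more called members, or called itself, up to 4 called members with the largest change are named. Xist, Ddx3y, Kap, Slco1a1, Slc7a12, Slc7a13, Cyp4a14, Cyp4b1, Prlr, Esr1, Prom1, Havcr1 and Lcn2 are named in every comparison. Where fewer than 5 genes are called, the 5 with the smallest p in each direction are named as not having passed. Of the genes this rule names, 3 are not reported here, though they stay in the tests and list counts. Any other gene is said to have been chosen after its values were seen. The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined.

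The change after ovariectomy was set against the difference between the sexes by a least squares slope through 0 over genes called at 2-fold or more between sham females and males. A slope of 0 means no movement along the sex difference and a slope of 1 a full move to the male level. The sham female libraries enter both axes, so their covariance was set beside 100 simulated draws of unchanged groups that share these libraries. The slope was also recomputed with sex genes chosen on 2 sham female libraries and the change measured against the remaining one, each in turn.

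The fit was tested on simulated data, with 50 changed genes per fold and comparison. All folds of a comparison were planted together, in genes with a mean log2(FPKM + 1) above 2, with noise independent between genes. It recovered 46.0% to 62.0% of 1.5-fold changes, 88.0% to 92.0% of 2-fold changes, 92.0% to 98.0% of 3-fold changes and 94.0% to 98.0% of 4-fold changes, and called 5 to 10 unchanged genes of 13083 to 13096 tested. Within groups, libraries correlated across tested genes at 0.979 to 0.987. Replicate numbers of the female groups were checked for pairing. Residuals of same-numbered sham and ovariectomized libraries correlated at 0.35, 0.17 and 0.29 across genes, and those of differently numbered ones at -0.33 to 0.05, so a fit with replicate number as a block is among the alternatives.

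Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 FPKM, scaling to a common sum (TPM), median-ratio scaling, quantile normalization, a replicate block, a fit of only the 2 groups compared, array weights, camera with an estimated correlation, and each library left out in turn. A marker score as a covariate, empirical Bayes without a trend, and a block over only the 2 female groups were added after seeing the data. The marker score is the mean log2(FPKM + 1) of 76 tested markers from the lists of cell types other than proximal tubule. Of these 10 lists, that of T, B and NK cells and neutrophils had 0 tested members, so those cells do not enter the score. Genes under the filter, Havcr1 and Lcn2 among them, were left out of the tests.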

Results

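Gene expression was measured in 9 libraries of prominin-1-positive cells from mouse kidney cortex, which the labels describe as proximal tubule, the nephron segment that reclaims most filtered solutes. Sham-operated males, sham-operated females and ovariectomized females contributed 3 libraries each. Estimated depths were 23.75, 22 and 24.25 M reads in the males, 27.75, 23 and 28.25 M in the sham females, and 25, 22.25 and 21.5 M in the ovariectomized females. Between 12287 and 13115 genes per library reached 1 FPKM. The first principal component held 48.2% of the variance and placed the males at -39.6 to -27.6, the sham females at 7.2 to 24.0 and the ovariectomized females at 10.5 to 21.7. Expression is given as mean FPKM ± SD over the 3 libraries of a group.

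The first comparison, sham females against sham males, asked which genes of these cells differ between the sexes. Female cells held far more Ugt1a2, which encodes a glucuronosyltransferase that conjugates drugs, more Cyp4a14, which encodes a fatty acid hydroxylase, and more Prlr, the prolactin receptor gene. Male cells held far more of the P450 genes Cyp2j13 and Cyp4b1, of the acidic amino acid transporter gene Slc7a13 and of Kap, which encodes kidney androgen-regulated protein. Lists for gluconeogenesis, drug transport and conjugation were on balance higher in females, as was that for fatty acid oxidation (adjusted p = 0.0613 with an estimated correlation). Lists of distal nephron markers were lower in the female fractions (adjusted p = 0.337 to 0.51 with an estimated correlation), and Prom1, the gene of the sorted protein, was higher.

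Of 13160 genes tested, 563 were higher and 641 lower in sham females, of which 137 and 120 differed by 2-fold or more. An unadjusted p under 0.05 was reached by 3506 genes (26.6%), and 3982 genes (30.3%) had libraries that did not overlap between the groups, where chance gives 10%. The share of called genes higher in females was 46.8% as deposited, 61.8% after median-ratio scaling (796 higher and 491 lower) and 59.6% after quantile normalization (695 and 471). The count moved with the library left out. The total of 1204 called genes was 1579, 600 and 601 without sham male libraries 1, 2 and 3. It was 1203, 561 and 732 without sham female libraries 1, 2 and 3. Each such fit has fewer libraries in a group, so a fall need not come from the library removed. Genes lower by 2-fold or more numbered 75 without sham male library 2, 183 without sham male library 1 and 251 without sham female library 1.

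Ugt1a2 (ENSMUSG00000090171, chromosome 1, 88200601 to 88218997) had the largest difference among the named genes on the log2(FPKM + 1) scale, which shrinks differences from values near 0. It was at 1084 ± 69.1 FPKM in sham females and 3.77 ± 0.933 in males (log2 fold change 7.85, adjusted p = 1.45e-09). The Ugt1a genes share all but their first exon, so reads from the shared exons were divided among them by estimate. Cyp4a14 (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142) was at 357 ± 22.8 FPKM against 7.43 ± 5.81 (log2 fold change 5.75, adjusted p = 0.000196). Prlr (ENSMUSG00000005268, chromosome 15, 10177238 to 10349180) was at 75.5 ± 5.86 against 0.917 ± 0.255 (5.33, adjusted p = 4.50e-08). Hpd, a tyrosine catabolism gene, was at 149.8 ± 28.4 FPKM in sham females and 4.58 ± 0.921 in males, and the retinol dehydrogenase gene Rdh16f2 at 443 ± 8.98 and 20.1 ± 13.2. Slc22a19, an organic anion transporter gene, and Serpina1f, a serpin gene, had log2 fold changes of 3.51 and 3.39. Among genes higher in males, Cyp2j13 (ENSMUSG00000028571, chromosome 4, 96027534 to 96077546) was at 0.400 FPKM in sham females and 98.8 ± 7.87 in males (-6.15, adjusted p = 1.45e-09). Slc7a13 (ENSMUSG00000041052, chromosome 4, 19818725 to 19842218) was at 0.170 ± 0.0889 and 47.8 ± 5.48 (-5.38, adjusted p = 3.50e-08). The fatty acid hydroxylase gene Cyp4a12a, the organic anion transporter gene Slco1a1, the carboxylesterase gene Ces1f and the acyl-CoA synthetase gene Acsm3 were lower in females, at log2 fold changes of -4.50, -4.40, -4.19 and -4.16. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762) was at 1742 ± 489 FPKM in sham females and 8719 ± 2297 in males (-2.33, adjusted p = 0.00217).

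**Figure D1:**
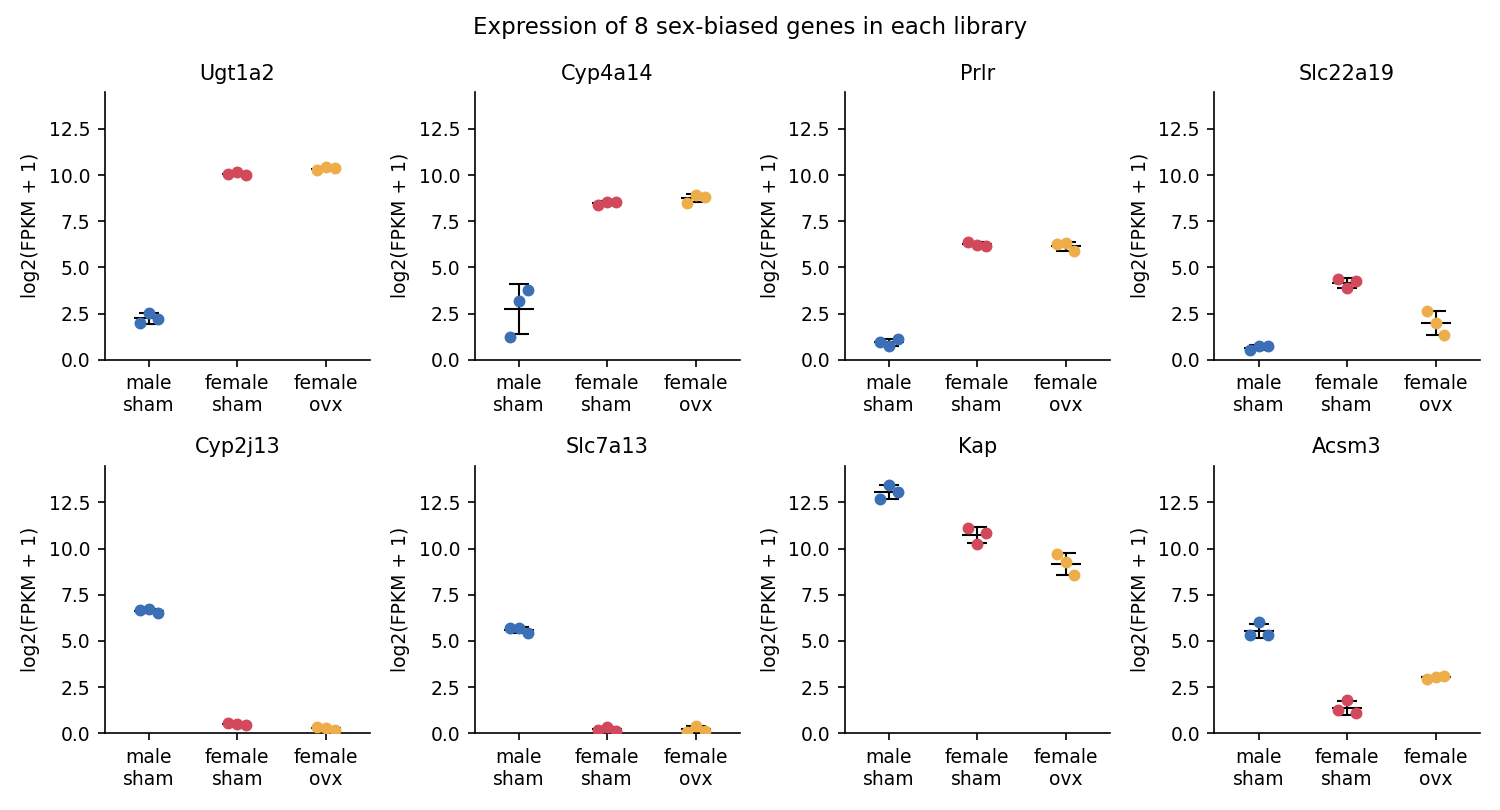
Log2(FPKM + 1) of Ugt1a2, Cyp4a14, Prlr, Slc22a19, Cyp2j13, Slc7a13, Kap and Acsm3 in the 3 groups, where points are libraries and bars the mean ± SD. Ugt1a2 averaged 3.77 FPKM in sham males, 1084 in sham females and 1306 in ovariectomized females.

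Sex chromosome genes separated the groups by sex. Xist, the RNA that silences an X chromosome, was at 36.3 ± 3.47 FPKM in sham females and 0.0167 in males. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d, housekeeping partners of X-linked genes, were listed at 0 in every female library. They were at 23.2 ± 2.42, 13.97 ± 0.841 and 4.64 ± 0.196 FPKM in males, where Uty was at 6.06 ± 0.431 against 0.0100 in sham females. In the Y-linked list 4 of 4 members were lower, with 4 adjusted over the list alone (camera adjusted p = 7.09e-11). In the X inactivation and escape list 4 of 6 members were higher, with 4 adjusted over the list alone (adjusted p = 5.60e-08), among them the translation factor gene Eif2s3x (log2 fold change 0.77). Of the male-higher genes known from earlier work, 14 of 17 members were lower, with 2 higher and 15 lower adjusted over the list alone (adjusted p = 7.78e-16), and of the female-higher genes 8 of 10 members were higher, with 9 higher and 1 lower adjusted over the list alone (adjusted p = 4.27e-14). The tryptophan catabolism gene Kynu, in the latter list, was at 33.7 ± 2.54 FPKM in sham females and 2.71 ± 0.765 in males. These 4 list calls held with an estimated correlation.

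Markers of other nephron segments were lower in the sham female fractions. Among thick ascending limb markers 1 of 9 members were higher and 4 lower, with 1 and 6 adjusted over the list alone (adjusted p = 0.0368), but adjusted p = 0.51 with an estimated correlation (range over alternatives 0.00263 to 0.791). This call was also lost without sham male library 2 (0.0927), sham male library 3 (0.0631) or sham female library 3 (0.089), and with a replicate block (0.0715). Among distal convoluted tubule markers 4 of 8 members were lower, with 7 adjusted over the list alone (adjusted p = 0.000953), but adjusted p = 0.365 with an estimated correlation (range over alternatives 3.08e-05 to 0.365). In collecting duct principal cells 4 of 7 members were lower, with 7 adjusted over the list alone (adjusted p = 0.000786), but adjusted p = 0.337 with an estimated correlation (range over alternatives 4.61e-05 to 0.337). In intercalated cells 5 of 9 members were lower, with 9 adjusted over the list alone (adjusted p = 0.000166), but adjusted p = 0.337 with an estimated correlation (range over alternatives 3.77e-06 to 0.337). Slc12a3, the thiazide-sensitive sodium chloride transporter gene, was at 242 ± 99.7 FPKM in sham females and 549 ± 83.0 in males (log2 fold change -1.24, adjusted p = 0.0246). Its call was lost without sham male library 2 (0.0831) or 3 (0.0899) or sham female library 2 (0.0842) or 3 (0.077), in a range over alternatives of 0.00455 to 0.395. The pendrin gene Slc26a4 had a log2 fold change of -1.20, and lost its call without the same 4 libraries (0.0947, 0.0771, 0.0694 and 0.0606, range over alternatives 0.0122 to 0.383).

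Prom1 (ENSMUSG00000029086, chromosome 5, 43993620 to 44102032) was at 98.6 ± 26.9 FPKM in sham females and 45.4 ± 8.11 in males (log2 fold change 1.09, adjusted p = 0.00671). The centred marker score of other cell types was 0.283, 0.644 and 0.357 in the male libraries, 0.094, -0.200 and -0.757 in the sham females, and 0.231, -0.358 and -0.296 in the ovariectomized females. Of its 76 marker genes, 4 are also in another list. With this score as a covariate, chosen after seeing the data, 252 genes were higher and 144 lower in sham females, and Prom1 was no longer called (0.69, adjusted p = 0.155, range over alternatives 0.00229 to 0.155), nor was Kap (-1.82, adjusted p = 0.0657, range 0.00109 to 0.0657). Of 26 list calls 16 held with the covariate, and of those lost, the thick ascending limb, distal convoluted tubule and endothelial markers are themselves part of the score. Early proximal tubule markers were higher in females on balance, where 3 of 10 members were higher, with 3 adjusted over the list alone (adjusted p = 0.000497), but adjusted p = 0.29 with an estimated correlation (range over alternatives 9.61e-06 to 0.531) and 0.531 with the covariate. The organic anion transporter gene Slc22a8 led them (1.11). Late segment (S3) markers went both ways, as 5 of 7 members were higher and 2 lower, with 5 and 2 adjusted over the list alone (adjusted p = 0.00757, direction up), but adjusted p = 0.314 with an estimated correlation (range over alternatives 2.26e-06 to 0.314). Fry gave the opposite direction for this list (adjusted p = 0.0699).

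**Figure D2:**
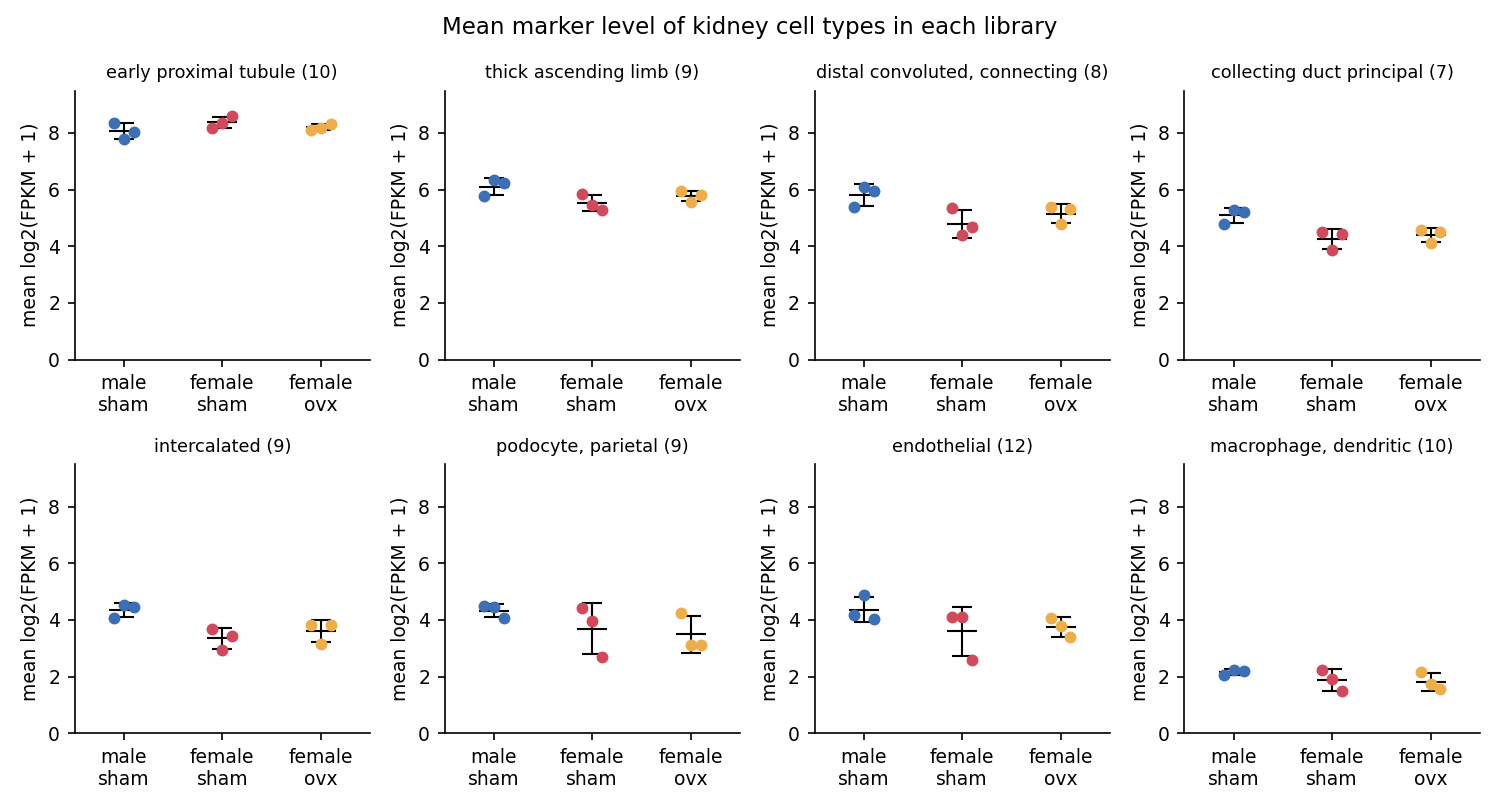
Mean log2(FPKM + 1) of the tested markers of 8 kidney cell types or tissues per library (points), with the mean ± SD of each group. Distal convoluted tubule markers lay -1.01 (SE 0.357) and intercalated cell markers -0.99 (SE 0.257) on the log2 scale from the male level in sham females.

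Transporter genes differed in both directions. Among organic anion, cation and drug transporters 15 of 31 members were higher and 5 lower, with 18 and 6 adjusted over the list alone (adjusted p = 1.32e-08), a call that held with an estimated correlation. Slc22a13, a nicotinate and urate exchanger gene, was at 12.5 ± 1.52 FPKM in sham females and 0.500 ± 0.295 in males (3.18), while the related Slc22a30 was at 4.56 ± 0.550 and 44.2 ± 1.85 (-3.03). Among amino acid transporters 7 of 21 members were higher and 2 lower, with 7 and 3 adjusted over the list alone (adjusted p = 5.76e-05), but adjusted p = 0.109 with an estimated correlation (range over alternatives 1.08e-08 to 0.109) and 0.0901 with the marker covariate. The list's median was 0.284 and ranged from -0.024 to 0.483 over the alternatives. Slc7a12, a cationic and neutral amino acid transporter homologue, was at 8.53 ± 4.22 FPKM in sham females and 0.247 ± 0.0208 in males. The glutamine transporter gene Slc38a3 and the glycine transporter gene Slc6a18 had log2 fold changes of 2.66 and 2.49. Among genes of glucose, phosphate, ion and water transport 9 of 29 members were higher and 1 lower, with 10 and 1 adjusted over the list alone (adjusted p = 5.61e-07), which held with an estimated correlation. The sodium-coupled sugar transporter genes Slc5a10 and Slc5a1, the dicarboxylate transporter gene Slc13a2 and the water channel gene Aqp1 were higher in females by 1.66, 1.48, 1.49 and 1.32.

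Metabolic lists were higher in females. Among gluconeogenesis, fructose and ammonia genes 6 of 15 members were higher, with 6 adjusted over the list alone (adjusted p = 4.51e-05), which held with an estimated correlation and with the marker covariate. Pck1 (ENSMUSG00000027513, chromosome 2, 173153048 to 173159273), the gene of the rate-setting enzyme of gluconeogenesis, was at 2489 ± 231 FPKM in sham females and 931.5 ± 78.9 in males (1.42, adjusted p = 4.89e-05). The glutamate dehydrogenase gene Glud1 and the fructokinase gene Khk had log2 fold changes of 0.60 and 0.49. Among fatty acid oxidation and PPAR alpha targets 18 of 34 members were higher and 2 lower, with 24 and 3 adjusted over the list alone (adjusted p = 1.11e-14), but adjusted p = 0.0613 with an estimated correlation (range over alternatives 8.45e-18 to 0.0613). Within it the hydroxylase gene Cyp4a10 was at 323 ± 8.51 FPKM in sham females and 38.7 ± 15.0 in males, while the fatty acid uptake gene Cd36 was at 5.05 ± 1.65 and 43.6 ± 9.30. Among cholesterol synthesis genes 3 of 23 members were higher, with 3 adjusted over the list alone (adjusted p = 0.000328), but adjusted p = 0.314 with an estimated correlation (range over alternatives 0.00014 to 0.314). The sterol demethylase gene Cyp51 and the sterol carrier gene Stard4 were higher by 1.32 and 0.74. All 3 lists kept their call with the marker covariate.

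Detoxification genes were split between the sexes. Among cytochrome P450 enzymes 5 of 29 members were higher and 11 lower, with 7 and 15 adjusted over the list alone, and camera did not call the list (adjusted p = 0.176) while fry did, as lower (adjusted p = 1.29e-06). Cyp4b1 (ENSMUSG00000028713, chromosome 4, 115624725 to 115647723), a fatty acid and xenobiotic hydroxylase gene, was at 111 ± 22.9 FPKM in sham females and 1345 ± 179 in males (-3.60, adjusted p = 5.23e-06). Among phase II conjugation enzymes 14 of 37 members were higher and 5 lower, with 15 and 7 adjusted over the list alone (adjusted p = 7.52e-07), which held with an estimated correlation. Acsm3 was at 1.66 ± 0.709 FPKM in sham females and 46.8 ± 13.9 in males, and the glucuronosyltransferase genes Ugt2b37 and Ugt2b38 had log2 fold changes of -3.33 and -2.40. Among NRF2 targets 5 of 19 members were higher and 1 lower, with 8 and 2 adjusted over the list alone (adjusted p = 0.00511), but adjusted p = 0.0816 with an estimated correlation (range over alternatives 0.00306 to 0.0816) and 0.0542 with the marker covariate. The efflux pump gene Abcc4 and the quinone reductase gene Nqo1 were higher by 1.62 and 0.75. Among iron and ferroptosis genes 3 of 13 members were higher, with 3 adjusted over the list alone (adjusted p = 0.00192), but adjusted p = 0.109 with an estimated correlation (range over alternatives 0.00113 to 0.109). The polyamine acetyltransferase gene Sat1, in that list, was higher by 0.40.

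The hormone receptor list was called up in females, where 3 of 6 members were higher and 1 lower, with 3 and 1 adjusted over the list alone (adjusted p = 0.000786), but adjusted p = 0.133 with an estimated correlation (range over alternatives 0.000349 to 0.133). Prlr is a member of this list, whose median log2 fold change was 0.270 and mean 0.997. Esr1, the estrogen receptor alpha gene, was near the detection filter at 0.913 ± 0.176 and 0.633 ± 0.116 FPKM (adjusted p = 0.365) and was not called. Among renin-angiotensin and brush border peptidase genes 4 of 13 members were higher, with 4 adjusted over the list alone (adjusted p = 0.000283), but adjusted p = 0.0781 with an estimated correlation (range over alternatives 7.64e-05 to 0.0781). The meprin gene Mep1a was higher by 0.95. Among proximal tubule transcription factors 4 of 16 members were higher and 1 lower, with 4 and 1 adjusted over the list alone (adjusted p = 0.0303), but adjusted p = 0.365 with an estimated correlation (range over alternatives 0.00272 to 0.39). That call was lost without sham male library 2 (0.125) or 3 (0.151) or sham female library 3 (0.0508), and with the marker covariate (0.39). The lipid sensor gene Ppara was higher by 0.82 and lost its call with the covariate (0.69, adjusted p = 0.073, range over alternatives 0.00141 to 0.073).

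Lists of immediate early, cell cycle, oxidative phosphorylation and endothelial genes were called near the threshold. Of immediate early genes 1 of 25 members were higher and 1 lower, with 1 and 2 adjusted over the list alone (adjusted p = 0.0418, direction down), but adjusted p = 0.537 with an estimated correlation (range over alternatives 0.000977 to 0.537) and lost calls without sham male library 1 (0.0665) or 2 (0.163) or sham female library 3 (0.412). With the marker covariate its median was 0.03 (adjusted p = 0.455). Among cell cycle genes 2 of 18 members were lower, with 1 higher and 3 lower adjusted over the list alone (adjusted p = 0.0418, direction down), but adjusted p = 0.42 with an estimated correlation (range over alternatives 0.000206 to 0.576). This call was lost without any one of sham male libraries 1, 2 and 3 (0.0859, 0.274 and 0.125) and sham female libraries 1 and 2 (0.0541 and 0.0829), with the marker covariate (0.23) and with a filter at 5 FPKM (0.576). For nuclear oxidative phosphorylation genes limma called 0 of 25 members (2 higher and 2 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), and the list was called up at a median log2 fold change of 0.03 (adjusted p = 0.0363), but adjusted p = 0.528 with an estimated correlation (range over alternatives 0.000584 to 0.528). Its median was -0.05 after quantile normalization, and the call was lost without sham male library 1 (0.153) or 2 (0.14) or sham female library 1 (0.0624) or 3 (0.102) and with the marker covariate (0.182). In the endothelial marker list limma called 0 of 12 members (1 lower at an unadjusted p under 0.05, 0 adjusted over the list alone), and the list was called down (adjusted p = 0.047), but adjusted p = 0.596 with an estimated correlation (range over alternatives 0.00283 to 0.596). It was lost without sham male library 1 (0.0859) or 2 (0.207), sham female library 3 (0.433) or ovariectomized library 2 (0.0656).

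Camera did not call the other lists, while fry called 22 lists in this comparison. Of tubular injury genes 2 of 16 members were higher and 4 lower, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.0549, fry adjusted p = 0.047, down). Il34, a macrophage growth factor gene, was at 1.70 ± 0.406 FPKM in sham females and 8.49 ± 0.353 in males, and Spp1, the osteopontin gene, at 1334 ± 118 and 653 ± 34.2. The injury genes Havcr1 and Lcn2 did not reach the filter. In polyamine metabolism 2 of 10 members were higher and 1 lower, with 3 and 1 adjusted over the list alone (adjusted p = 0.0659), with the ornithine decarboxylase gene Odc1 lower (-0.64). In the growth hormone and STAT5 list 2 of 11 members were higher and 1 lower, with 2 and 1 adjusted over the list alone (adjusted p = 0.107), where the median was 0.10 and the mean -0.01. For vitamin D and calcium handling 3 of 19 members were higher and 4 lower, with 4 and 5 adjusted over the list alone (adjusted p = 0.125), where the median was 0.11 and the mean -0.07. The liver, fat and ovary markers were at adjusted p = 0.144, and 2 of 3 members were higher and 1 lower, with 2 and 1 adjusted over the list alone. Albumin (Alb) was higher by 1.44 and transthyretin (Ttr) lower, at -1.34. Circadian clock (0.054), interferon response (0.235) and matrix genes (0.105) did not pass camera. Complement genes did not pass it either (0.408), and fry called them down (adjusted p = 0.0139). The unfolded protein response (0.105), mitochondrially encoded genes (0.509, where camera pointed up and the median was -0.03), and markers of podocytes (0.385), fibroblasts (0.892), macrophages (0.4) and red blood cells (0.145) were not called by camera.

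With 3 libraries per group, simulated 1.5-fold changes were recovered for 46.0% of genes in this comparison and 2-fold changes for 88.0%. Sex and the share of other cells in the fractions differed together. No day of surgery is given for the males, so a difference in it could not be told apart from sex.

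The second comparison, ovariectomized against sham females, asked which genes change when the ovaries are removed at postnatal day 21. In the main fit only Pllp, which encodes the membrane proteolipid plasmolipin, passed the test, and it was lower after ovariectomy. The genes that mark female cells against male ones, such as Ugt1a2, Cyp4a14 and Prlr, stayed at levels far from those of males. The organic anion transporter genes Slc22a19 and Slc22a26 had lower values and the conjugation genes Ugt1a10 and Acsm3 higher values after ovariectomy, and none of the 4 passed the test. As a list, phase II conjugation enzymes were higher and female-higher genes from earlier work lower, though no list call held with an estimated correlation.

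Pllp (ENSMUSG00000031775, chromosome 8, 94674894 to 94696278) was at 16.9 ± 0.369 FPKM in ovariectomized and 41.0 ± 2.42 in sham females (log2 fold change -1.23, adjusted p = 0.0417), lower in all 3 libraries. Its call was lost without sham male library 3 (0.0719), sham female library 1 (0.308) or 3 (0.221), or ovariectomized library 1 (0.159), 2 (0.199) or 3 (0.204). It was also lost without the filter (0.0837), after scaling to a common sum (0.0575), median-ratio scaling (0.0503) or quantile normalization (0.0600), and with the replicate block (0.0575), in a range over alternatives of 0.00234 to 0.308. Among genes higher after ovariectomy limma called 0, and an unadjusted p under 0.05 was reached by 828 genes (6.3%), 25 genes had an adjusted p under 0.10, and 1692 genes (12.9%) did not overlap between the groups, where chance gives 10%. The number of calls also moved with single libraries. It was 3 higher and 5 lower without sham male library 1, 2 and 1 without sham male library 2, 7 and 2 without sham female library 2, and 1 lower without ovariectomized library 1. Without sham male library 3, sham female library 1 or 3, or ovariectomized library 2 or 3, no gene was called. A replicate block over only the 2 female groups, added after seeing the data, called 3 higher and 3 lower, Pllp among the latter, and 13 lists.

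The genes with the smallest p beyond Pllp did not pass in the main fit. Slc22a26 (ENSMUSG00000053303, chromosome 19, 7781041 to 7802667), an organic anion transporter gene, was at 0.690 ± 0.265 FPKM in ovariectomized and 4.24 ± 0.741 in sham females (log2 fold change -1.63, adjusted p = 0.0558). Its neighbour Slc22a19 was at 3.26 ± 1.93 and 17.2 ± 3.24 (-2.18). The ferritin light chain gene Ftl1, which stores iron, was at 2672 ± 39.1 and 3615 ± 55.1 (-0.44). The microRNA gene Mir681 was listed at 0 in all ovariectomized libraries and at 1.09 ± 0.130 FPKM in sham females. It spans only 69763835 to 69763944 on chromosome 12, so at the estimated depths its values stand for very few reads. Ugt1a10 (ENSMUSG00000090165, chromosome 1, 88055388 to 88219004), whose last exons are shared with Ugt1a2, was at 84.9 ± 5.13 and 16.4 ± 8.36 (2.42). Rarres2, the chemerin gene, was at 49.5 ± 4.53 and 14.6 ± 4.07 (1.73). Acsm3, higher in males, was at 7.18 ± 0.516 and 1.66 ± 0.709 (1.65), the methyltransferase gene Bhmt at 26.6 ± 3.40 and 14.6 ± 0.799 (0.82), and the protease inhibitor gene Serpina1d at 5.68 ± 2.40 and 1.14 ± 0.300 (1.60). Each of the 8 genes after Slc22a26 had an adjusted p of 0.0659. Some alternatives did call such genes. Of the 21 genes named in this comparison, 8 gained a call with array weights, 7 with a pseudocount of 5 and 2 with a block over the 2 female groups.

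Of the genes named in every comparison, Kap was at 612 ± 233 FPKM in ovariectomized and 1742 ± 489 in sham females (-1.54, adjusted p = 0.214). Prlr was at 70.6 ± 11.6 and 75.5 ± 5.86 (adjusted p = 0.993), and Cyp4a14 at 435 ± 63.4 and 357 ± 22.8 (adjusted p = 0.996). Slc7a12 was at 4.62 ± 2.92 and 8.53 ± 4.22 (adjusted p = 0.799), and Cyp4b1 at 84.8 ± 19.7 and 111 ± 22.9 (adjusted p = 0.824). Slco1a1 (0.00667 and 0.0100 FPKM) and Slc7a13 (0.160 and 0.170) remained near 0 in both female groups. The receptor gene Esr1 (1.27 ± 0.326 and 0.913 ± 0.176) was not called (adjusted p = 0.933). Xist was at 39.4 ± 3.25 and 36.3 ± 3.47, Ddx3y was listed at 0 in all 6 female libraries, and Prom1 was at 74.4 ± 5.23 and 98.6 ± 26.9 (adjusted p = 0.831).

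Of 42 lists, camera called 6 after ovariectomy. None of them held with an estimated correlation (0 lists called), and fry called 2 lists, phase II enzymes and cytochrome P450 enzymes (adjusted p = 0.0042 and 0.0497, both up). Phase II conjugation enzymes were higher at a median log2 fold change of 0.17 (adjusted p = 0.000203), but adjusted p = 0.0974 with an estimated correlation (range over alternatives 2.40e-05 to 0.0974). In this list limma called 0 of 37 members (14 higher and 3 lower at an unadjusted p under 0.05, 11 higher and 2 lower adjusted over the list alone). Among those passing over the list alone were Ugt1a10, Acsm3 and the glutathione transferase genes Gsta3 (0.57) and Gsta4 (0.56), the last 2 chosen after their values were seen. Female-higher genes from earlier work were lower at a median of -0.58 (adjusted p = 8.88e-05), but adjusted p = 0.496 with an estimated correlation (range over alternatives 2.78e-06 to 0.496). There limma called 0 of 10 members (4 lower at an unadjusted p under 0.05, 3 lower adjusted over the list alone). The last 3 were Slc22a19, Slc22a7 and the P450 gene Cyp2a4, of which Slc22a7 and Cyp2a4 were chosen after their values were seen. Immediate early genes were higher at a median of 0.29, with 23 of 25 above 0 (adjusted p = 6.60e-05), and adjusted p = 0.808 with an estimated correlation (range over alternatives 9.05e-08 to 0.808). Their call was lost without sham female library 3 (0.103), and limma called 0 of 25 members (1 higher at an unadjusted p under 0.05, 0 adjusted over the list alone). Cell cycle genes were lower at a median of -0.23 (adjusted p = 0.00424), but adjusted p = 0.808 with an estimated correlation (range over alternatives 0.000771 to 0.926). In that list limma called 0 of 18 members (4 lower at an unadjusted p under 0.05, 2 lower adjusted over the list alone). With a filter at 5 FPKM its call was lost and its median was 0.13 (adjusted p = 0.926).

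Nuclear oxidative phosphorylation genes were higher after ovariectomy at a median of only 0.06 with 24 of 25 above 0 (adjusted p = 0.00112), but adjusted p = 0.808 with an estimated correlation (range over alternatives 0.000103 to 0.977). The median was 0.005 after quantile normalization, where camera pointed down, and limma called 0 of 25 members (1 higher at an unadjusted p under 0.05, 0 adjusted over the list alone). Distal convoluted tubule markers were higher in the ovariectomized fractions at a median of 0.38 (adjusted p = 0.0348), but adjusted p = 0.808 with an estimated correlation (range over alternatives 2.88e-05 to 0.808). Their call was lost without sham female library 2 (0.302) or 3 (0.109) or ovariectomized library 1 (0.105) or 3 (0.21), and with the replicate block (0.0579), and limma called 0 of 8 members (also 0 at an unadjusted p under 0.05, 0 adjusted over the list alone). Among the 36 lists not called, the organic anion transporters had a median of -0.03 (adjusted p = 0.227), and limma called 0 of 31 members (2 higher and 5 lower at an unadjusted p under 0.05, 4 lower adjusted over the list alone). These 4 were Slc22a19, Slc22a26, Slc22a7 and Slc22a27, the last 2 chosen after their values were seen. Male-higher genes from earlier work had a median of -0.10 and a mean of 0.06 (adjusted p = 0.456), and limma called 0 of 17 members (5 higher and 4 lower at an unadjusted p under 0.05, 3 higher and 3 lower adjusted over the list alone). Gluconeogenesis (0.0775), fatty acid oxidation (0.34) and early proximal tubule markers (0.0775) did not pass.

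In simulated data of this design, 56.0% of 1.5-fold and 92.0% of 2-fold changes were recovered. Those data held many changed genes, none at the lowest levels, which makes the adjusted threshold easier to pass than with 1 call. Changes above 2-fold, such as that of Slc22a19, did not pass here, so these shares do not bound what was missed. Other splits of the same 6 female libraries gave up to 13 called genes and 14 called lists, against 1 gene and 6 lists here, though those that part all 3 numbered pairs as this one does gave 0, 0 and 1 genes and 3, 5 and 6 lists.

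The values after ovariectomy were set against the sex difference over the 257 genes, Ugt1a2, Prlr, Kap and Cyp2j13 among them, that differed by 2-fold or more between sham females and males. The slope of the ovariectomy change on the male minus female difference was 0.011 (SD 0.020 over the ovariectomized libraries), where 1 would be a full move to the male level. It was 0.073 without sham female library 1, 0.044 without sham male library 1, 0.038 with a pseudocount of 0.1 and 0.070 over the lists known from earlier work. Over all 1204 called genes it was 0.025 (SD 0.033). With sex genes chosen without 1 sham female library and the change measured against that library, slopes were -0.050, 0.003 and -0.025 over 389, 210 and 245 genes. The covariance of both differences was 0.0488, against 0.0230 (SD 0.0048) in simulated unchanged groups that share the sham females. The simulated groups held no sex difference, so their SD is not the spread to expect over genes chosen for one. No excess is read from this covariance. Slc22a19 had a value nearer the male level after ovariectomy and Kap one further from it, and neither passed the test. Of 137 female-higher genes, 51 (37.2%) had an unadjusted p under 0.05 after ovariectomy, with 23 toward the male level and 28 away from it. Of 120 male-higher genes, 25 (20.8%) did, 11 toward and 14 away. These counts share the sham female libraries, and with no library in common, a test chosen after seeing the data, the 3 turns gave 20 toward and 39 away, 16 and 23, and 20 and 39.

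**Figure D3:**
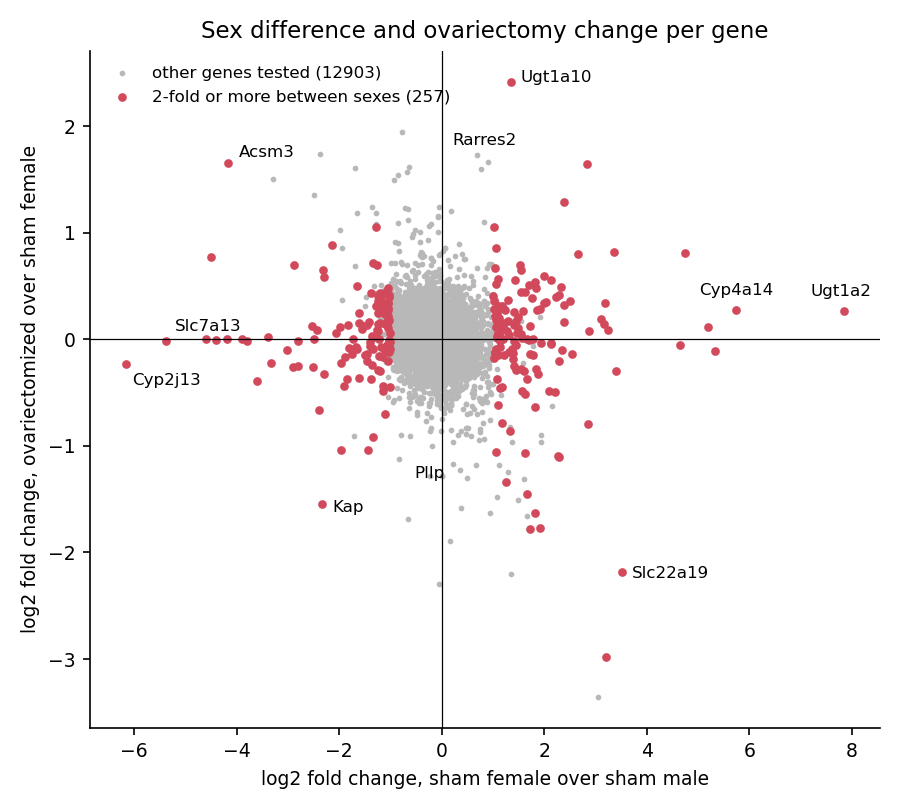
Log2 fold change of ovariectomized over sham females (y axis) against that of sham females over sham males (x axis) for 13160 genes, with the 257 genes called at 2-fold or more between the sexes in red and the other 12903 in grey. The slope on the male minus female difference over the 257 genes was 0.011, and 0.002 to 0.073 with 1 library left out.

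The third comparison, ovariectomized females against sham males, asked how much of the difference between the sexes is left without ovaries. Ugt1a2, Cyp4a14, Hpd and Prlr were still far higher than in males, and Cyp2j13, Slc7a13, Cyp4b1 and Kap still far lower. The conjugation list was again higher on balance, as were fatty acid oxidation and gluconeogenesis (adjusted p = 0.0758 and 0.0506 with an estimated correlation), each with most called members higher. Ccnd1, the cyclin D1 gene, was lower than in males, and the cell cycle list was called down, with 7 of 18 members lower and 1 higher (adjusted p = 0.278 with an estimated correlation).

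Of 13160 genes, 741 were higher and 814 lower in ovariectomized females, of which 162 and 133 by 2-fold or more. An unadjusted p under 0.05 was reached by 3770 genes (28.6%), and 4482 (34.1%) did not overlap between the groups, where chance gives 10%. The share higher was 47.7% as deposited, 64.6% after median-ratio scaling (978 higher and 535 lower) and 58.9% after quantile normalization (767 and 536). The total of 1555 was 1631, 952 and 877 without sham male libraries 1, 2 and 3. It was 1028, 880 and 896 without ovariectomized libraries 1, 2 and 3. Of the 563 and 641 genes higher and lower in sham females, 466 and 426 were also called here in the same direction, where independence gives 31.7 and 39.6. At 2-fold or more the shared genes numbered 113 and 84. Both comparisons share the male libraries, so independence is not the value to expect, and their covariance over all genes tested was 0.1747 against 0.0159 in simulated unchanged groups that share them. Of the 137 female-higher and 120 male-higher genes, 123 and 95 were called against males in ovariectomized females.

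Ugt1a2 was at 1306 ± 77.0 FPKM in ovariectomized females and 3.77 ± 0.933 in males (log2 fold change 8.11, adjusted p = 1.07e-09), and Cyp4a14 was at 435 ± 63.4 (6.03). Hpd was at 260.4 ± 7.98 FPKM (5.56), Prlr at 70.6 ± 11.6 (5.22) and Rdh16f2 at 426 ± 23.2 (4.59). Serpina1a, a protease inhibitor gene of a family of close copies, was at 27.0 ± 7.26 against 0.233 ± 0.202 in males (4.48), and Bhmt at 26.6 ± 3.40 against 0.520 ± 0.131 (4.18). Cyp2j13 was at 0.193 ± 0.0702 FPKM (-6.39, adjusted p = 1.07e-09), Slc7a13 at 0.160 ± 0.148 (-5.40), Cyp4b1 at 84.8 ± 19.7 (-3.99) and Ces1f at 14.3 ± 0.876 (-4.18). Kap was at 612 ± 233 FPKM against 8719 ± 2297 in males (-3.87, adjusted p = 8.26e-05). Eif2s3y, Ddx3y, Uty and Kdm5d were listed at 0 in all ovariectomized libraries. Prom1 was higher than in males (0.71, adjusted p = 0.0357), a call lost without sham male library 1 (0.0762) or 2 (0.117) or ovariectomized library 1 (0.0637), 2 (0.106) or 3 (0.105), in a range over alternatives of 0.00924 to 0.298. Esr1 was at 1.27 ± 0.326 FPKM and 0.633 ± 0.116 in males and was not called (adjusted p = 0.0779).

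Of 42 lists, camera called 24 in ovariectomized females against males, 3 held with an estimated correlation, and fry called 17. Of lists camera did not call, fry called P450 enzymes, complement genes and late segment (S3) markers as lower (adjusted p = 4.05e-06, 0.0213 and 0.0281). The 3 that held were the X inactivation and escape list, the male-higher genes from earlier work and the phase II enzymes. Among phase II enzymes 16 of 37 members were higher and 6 lower, with 18 and 8 adjusted over the list alone (adjusted p = 5.37e-08), with Ugt1a10 higher by 3.76 and Ugt2b38 at -3.06. Of male-higher genes 15 of 17 members were lower, with 15 adjusted over the list alone (adjusted p = 5.82e-16), and of the X-linked list 4 of 6 members were higher, with 4 adjusted over the list alone (adjusted p = 1.47e-06). In the Y-linked list 4 of 4 members were lower, with 4 adjusted over the list alone (adjusted p = 7.22e-10), but adjusted p = 0.0506 with an estimated correlation (range over alternatives 3.24e-14 to 0.0506). Of female-higher genes 6 of 10 members were higher and 1 lower, with 6 and 1 adjusted over the list alone (adjusted p = 8.56e-08), but adjusted p = 0.0792 with an estimated correlation (range over alternatives 1.17e-09 to 0.0792). Among fatty acid oxidation genes 21 of 34 members were higher and 2 lower, with 24 and 2 adjusted over the list alone (adjusted p = 5.93e-15), but adjusted p = 0.0758 with an estimated correlation (range over alternatives 1.29e-18 to 0.0758). In gluconeogenesis 7 of 15 members were higher, with 8 higher and 1 lower adjusted over the list alone (adjusted p = 1.57e-05), but adjusted p = 0.0506 with an estimated correlation (range over alternatives 1.14e-06 to 0.0506). Pck1 was at 2741 ± 288 FPKM (1.55), and Khk and Glud1 were higher by 0.74 and 0.78. Among organic anion transporters 14 of 31 members were higher and 5 lower, with 15 and 7 adjusted over the list alone (adjusted p = 1.83e-05), but adjusted p = 0.0758 with an estimated correlation (range over alternatives 6.97e-07 to 0.0758). The steroid transporter homologue Slc22a29 was at 39.5 ± 5.18 FPKM against 4.28 in males. In glucose, phosphate, ion and water transport 9 of 29 members were higher, with 9 higher and 2 lower adjusted over the list alone, and the list was called up (adjusted p = 0.000239) at a median of -0.03 and a mean of 0.33, with adjusted p = 0.117 with an estimated correlation (range over alternatives 4.79e-06 to 0.117). The dicarboxylate transporter gene Slc13a3 was higher by 1.67.

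Amino acid transporters were higher on balance, where 8 of 21 members were higher and 2 lower, with 8 and 4 adjusted over the list alone (adjusted p = 0.0037), but adjusted p = 0.278 with an estimated correlation (range over alternatives 3.24e-06 to 0.278), and Slc38a3 was at 25.8 ± 1.73 FPKM against 1.42 ± 0.0306. The list's median was 0.184 and ranged from -0.118 to 0.341 over the alternatives. Hormone receptors, Prlr among them, were called up (adjusted p = 0.00252), but adjusted p = 0.198 with an estimated correlation (range over alternatives 0.000751 to 0.198). Their median was 0.344 and their mean 1.049. Cholesterol synthesis (0.000363), but adjusted p = 0.315 with an estimated correlation (range over alternatives 3.62e-05 to 0.315), and NRF2 targets (0.00695), but adjusted p = 0.108 with an estimated correlation (range over alternatives 0.00473 to 0.108), were also called up, with Abcc4 at 67.8 ± 1.40 FPKM against 15.7 ± 3.84 in males. Brush border peptidases were called up (adjusted p = 0.00772), but adjusted p = 0.198 with an estimated correlation (range over alternatives 0.00184 to 0.198). Iron genes were called up (adjusted p = 0.0309), but adjusted p = 0.278 with an estimated correlation (range over alternatives 0.0126 to 0.278), and lost their call without sham male library 2 (0.103) or ovariectomized library 1 (0.0508). Circadian genes were called up (adjusted p = 0.0401), but adjusted p = 0.56 with an estimated correlation (range over alternatives 0.000896 to 0.56), and lost their call without sham male library 3 (0.406) or ovariectomized library 1 (0.0973) or 2 (0.0728). Proximal tubule transcription factors were called up (adjusted p = 0.0116), but adjusted p = 0.387 with an estimated correlation (range over alternatives 0.00109 to 0.387), and lost their call without sham male library 2 (0.063) or 3 (0.0523). Oxidative phosphorylation genes were called up at a median of 0.09 (adjusted p = 0.000106), but adjusted p = 0.408 with an estimated correlation (range over alternatives 6.76e-07 to 0.408), and their median was -0.03 after quantile normalization.

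Among cell cycle genes 1 of 18 members were higher and 7 lower, with 1 and 13 adjusted over the list alone (adjusted p = 0.00147, direction down), but adjusted p = 0.278 with an estimated correlation (range over alternatives 1.40e-07 to 0.785). With a filter at 5 FPKM the call was lost, at a median of -0.04 (adjusted p = 0.785). Ccnd1 was at 44.9 ± 7.46 FPKM in ovariectomized females and 94.1 ± 13.2 in males (-1.06, adjusted p = 0.00163). The polyamine gene Odc1 was at 212 ± 11.1 against 424 ± 19.8, and the phospholipid flippase gene Atp11a at 17.5 ± 1.78 against 71.8 ± 11.1 (-1.97). Matrix genes were called down (adjusted p = 0.0219), but adjusted p = 0.487 with an estimated correlation (range over alternatives 0.00265 to 0.487), and lost their call without ovariectomized library 3 (0.0608). Collecting duct markers (0.00659), but adjusted p = 0.487 with an estimated correlation (range over alternatives 0.000882 to 0.487), and intercalated cell markers (0.0065), but adjusted p = 0.502 with an estimated correlation (range over alternatives 0.000586 to 0.502), were lower in ovariectomized females. Distal convoluted tubule markers were called down (adjusted p = 0.0382), but adjusted p = 0.56 with an estimated correlation (range over alternatives 0.0078 to 0.56), and lost their call without sham male library 2 (0.104) or 3 (0.0753) or ovariectomized library 2 (0.129), and with the replicate block (0.0517). Early proximal tubule markers were called up (adjusted p = 0.0309), but adjusted p = 0.502 with an estimated correlation (range over alternatives 0.0017 to 0.934), and lost their call without sham male library 2 (0.238) or 3 (0.052) or ovariectomized library 2 (0.0543) or 3 (0.0729). With the marker score as a covariate, 462 genes were higher and 309 lower, and 17 of the 24 list calls held, where the distal convoluted tubule markers, which lost theirs, are part of the score.

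Sex and ovary status differ together in this comparison, and the day of surgery of the males is not given. Other-cell markers and Prom1 differed here in the same direction as between sham females and males.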

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

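The marker score covariate, the fit without a variance trend and the block over the 2 female groups were chosen after seeing the data. All other alternatives were planned, and depth estimated at 21.5 to 28.25 M reads limits genes near 1 FPKM. Scaling to TPM, a pseudocount of 5 and no filter kept all 26, 6 and 24 list calls of the 3 comparisons, while no filter weakened 37 of 101 and 26 of 96 named genes against males. Counts that stayed within 1.5 times are not listed, and where no reason is given the cause was not tested.

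Between sham females and males, genes lower by 2-fold or more were 209 with a pseudocount of 0.1, and a pseudocount of 5, which shrinks folds, gave 82 higher and 60 lower. Genes lower were 344 with no filter, where more genes are tested, and 344 with only the 2 groups compared, where fewer libraries are fitted. With an estimated correlation 8 lists were called. The marker covariate gave 252 higher and 144 lower, and weakened 47 of 101 named genes. Leaving out 1 library in turn gave 339 to 657 higher, 222 to 922 lower, 113 to 147 higher and 75 to 251 lower by 2-fold or more, and 20 to 28 lists.

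Between ovariectomized and sham females, a pseudocount of 5 gave 10 higher and 10 lower, of which 4 and 2 by 2-fold or more. No filter gave 1 higher. Genes lower were 0, and 0 by 2-fold or more, with scaling to TPM, median-ratio scaling, quantile normalization and the replicate block. Only the 2 groups gave 5 higher and 4 lower (2 and 2 by 2-fold or more), and array weights 5 and 8 (4 and 4). With an estimated correlation 0 lists were called. The marker covariate gave 1 higher and 3 lower, 3 of the latter by 2-fold or more, with 10 lists. The fit without a trend gave 3 lower, 3 by 2-fold or more. The block over 2 female groups gave 3 higher and 3 lower, 1 higher by 2-fold or more, with 13 lists. Leaving out 1 library gave 0 to 7 higher, 0 to 5 lower, 0 to 4 and 0 to 2 by 2-fold or more, and 5 to 12 lists.

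Between ovariectomized females and males, genes lower by 2-fold or more were 213 with a pseudocount of 0.1, and a pseudocount of 5 gave 93 higher and 60 lower. Genes lower were 535 with median-ratio scaling and 536 with quantile normalization. With an estimated correlation 3 lists were called. The marker covariate gave 462 higher and 309 lower, and weakened 31 of 96 named genes. Leaving out 1 library gave 479 to 752 higher, 364 to 879 lower, 153 to 165 and 94 to 143 by 2-fold or more, and 20 to 26 lists.

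The slope was 0.038 with a pseudocount of 0.1, 0.070 over the lists known from earlier work, -0.024 with split sham females, and 0.002 to 0.073 with 1 library left out. Immediate early genes between the sexes turned to 0.031 with the covariate, and endothelial markers, which are part of the score, to 0.287. A filter at 5 FPKM, with fewer genes tested, moved the cell cycle median after ovariectomy from -0.227 to 0.129. Quantile normalization turned oxidative phosphorylation genes to -0.052, 0.005 (camera pointing down) and -0.030 in the 3 comparisons. The lowest median of amino acid transporters over the alternatives was -0.024 in sham females and -0.118 in ovariectomized females, each against males. Values near 0 after ovariectomy turned for Slco1a1 (0.026 with quantile normalization, 0.001 with the covariate, -0.014 to 0.002 with 1 library left out) and for Slc7a13 (0.077 with quantile normalization, -0.120 to 0.044 with 1 library left out). With 1 library left out, Prlr ranged from -0.188 to 0.036. The replicate block ended the call of 1 list in each comparison, of 10 of 101 and 9 of 96 named genes against males, and of Pllp. With it 971 of 1204 and 1307 of 1555 genes called against males stayed called, and 28, 5 and 25 lists were called. The labels used here state no pairing by number of sham males with either female group. Residuals of same-numbered libraries of the males correlated at -0.13, 0.14 and 0.28 with sham females and -0.03, 0.02 and 0.07 with ovariectomized females. Those of differently numbered ones correlated at -0.36 to 0.28.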

Other observations

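The tests on other cells and on neighbouring genes, and leaving chromosome Y and overlapping genes out of the latter, were chosen after the result was seen, as were the tests with no library and no female number in common, and the other tests on low p after ovariectomy and on splits before.

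Sex differences sat next to each other in several gene clusters, picked here after their values were seen. On chromosome 19 a row of organic anion transporter genes alternated between the sexes, with log2 fold changes in sham females over males of 3.51 for Slc22a19, 1.82 for Slc22a26, 1.11 for Slc22a27, -1.84 for Slc22a28, 2.87 for Slc22a29 and -3.03 for Slc22a30. On chromosome 4 the fatty acid hydroxylase genes Cyp4a12a (-4.50) and Cyp4a12b (-2.32) were higher in males and Cyp4a14 (5.75), Cyp4a10 (3.11) and Cyp4a31 (1.73) in females. The steroid reductase genes Akr1c14 (-1.97) and Akr1c18 (1.92) went apart, while the carboxylesterase genes Ces1f (-4.19) and Ces1g (-2.51) and the drug efflux genes Abcb1a (1.91) and Abcb1b (2.39) went together. The betaine pathway genes Bhmt (3.36), Bhmt2 (1.42) and Dmgdh (1.99) were all higher in females.

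The sex difference and the other-cell markers moved together, so dilution by other cells in the male fractions, or RNA from other kidney cells, may account for some of it. Of 137 female-higher genes, 109 exceeded every early segment marker (highest 1.11, Slc22a8), which dilution forbids, and of 120 male-higher genes 28 exceeded every marker of another cell type (lowest -1.99, SE 1.17, Hba-a2). These bounds concern cells other than proximal tubule. Late segment (S3) markers, which went both ways, had a median of 1.480, and a different mix of proximal tubule segments was not tested. For the other 28 and 92 genes dilution or RNA from other cells cannot be told apart from sex, because sex and marker level are confounded. With the marker covariate 17 of these 28 stayed called and 39 of the 92, while 15 of all 28 and 53 of all 92, called or not, were at 2-fold or more, and in the 11 and 53 genes that lost their call the median fell in size (1.07 to 0.92 and -1.16 to -0.83) as the SE grew (0.182 to 0.266 and 0.253 to 0.322). All 257 kept their sign, but they were chosen on the same libraries for a large difference, so this tells little about the cause. Sex itself remains an untested explanation.

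Of the 257 sex genes 29.6% had an unadjusted p under 0.05 after ovariectomy, against 5.8% of other genes. Sham female libraries shared by both comparisons are argued against, because with sex genes chosen on other sham females, and ovariectomy tested against a single one with the spread of the other groups, the lowest ratio of the percents was 3.79, and spread shared through male and ovariectomized libraries is too, because with no library in common and the spread of the ovariectomized libraries alone it was 3.32. Female libraries with the same number deviating together are argued against. With sex genes from all males and 1 sham female, and ovariectomy tested on the 2 other female numbers, the lowest ratio was 3.55. Males of every number stayed in, so deviation shared with males of the same number was not removed. With the marker covariate the percent was 31.5% (6.8% of other genes), which argues against other cells in different shares only as far as the score tracks them. The score is a mean over many cell types, and collecting duct and intercalated cell markers kept their call between the sexes with it. Different shares of single cell types are therefore not excluded. That sex genes vary more between animals stays open, since 1 of 10 splits, the real one, had as high a percent, the next reached 14.8, and 29.6 lies at the bound of 2 times that set in advance, not beyond it, though the 3 other splits that part all numbered pairs, as the real one does, gave only 1.2, 5.1 and 1.6, and an effect of ovariectomy is a hypothesis only.

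Reads shared between near-identical neighbours could place sex differences side by side. Of neighbouring pairs outside chromosome Y, 9 were of different families, where random sets gave 3.51 on average and as many in 94 of 10000, and such genes do not share near-identical sequence. Within 1 family 7 pairs went in opposite directions, against the prediction that shared reads move both neighbours the same way. Families were assigned by the stem of the symbol, and how near-identical their members are was not checked. These pairs therefore cannot decide the question for near-identical genes. A division of shared reads that gives more to 1 gene and less to its neighbour was not tested. The 12 pairs of 1 family in the same direction cannot be told apart from shared reads, because reads were not analysed here. Control of neighbouring genes by sex was not tested.

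Each comparison has 10 splits of its 6 libraries, too few for a share under 0.05. Between sham females and males the real split was the only 1 to reach its count for genes (1204, highest other 2), for genes by 2-fold or more (257, 2) and for lists (26, 22), 1 of 10 each. Between ovariectomized females and males it was also 1 of 10 each (1555 genes and 0, 295 and 0, 24 lists and 19). Between ovariectomized and sham females, 5 splits gave at least 1 gene (highest other 13), 5 gave at least 1 by 2-fold or more (highest other 11) and 8 gave at least 6 lists (highest other 14). Splits that also part all 3 numbered pairs gave 0, 0 and 1 genes and 3, 5 and 6 lists. The split with 13 genes, picked after the counts were seen, set ovariectomized library 1 and sham female libraries 1 and 2 against the rest. The marker score of other cells also parted these sides, at 0.231, 0.094 and -0.200 against -0.296, -0.358 and -0.757. Any such score parts some split of the libraries, so whether these samples hold a structure other than surgery was not tested.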
